A study of Gallus gallus with 6 samples.

How the data were processed

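RNA sequencing was done on 6 libraries of HD11, a chicken macrophage-like cell line transformed by an avian myelocytomatosis virus. Per the labels, 3 libraries came from control cultures and 3 from cultures given dextran, which the series text calls dextran sulphate, a sulphated polysaccharide with a strong negative charge. The dose and the time of exposure are not given in the sources used here. Replicate numbers come from the sample titles. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

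The values came from 1 deposited table with 8545 rows of NCBI genes. Per the submitters' processing notes, HISAT2 2.2.1, Bowtie2 2.4.5 and RSEM 1.3.1 were used with the chicken build GRCg6a, and the role of each tool is not given in the sources used here. Per the file headers, the authors gave an estimated read count, as RSEM expected counts, for each gene and library. Of the count values, 9.01% were not whole, in 872 genes. Per the file headers the authors also gave TPM, a length-adjusted share of all transcripts, and FPKM, fragments scaled to gene length and library size, for the same libraries. The deposited log2 ratio of dextran over control equals the ratio of group means after division by a size factor per library: factors recovered from 5972 genes returned it with a median absolute difference of 0.000101. The program behind that ratio and behind the deposited p-value and q-value is not given in the sources used here. Every deposited q-value lay below 0.05, so the table holds genes that the authors had already called as different. For 8284 of the 8512 rows with a p above 0, the deposited q-value times its rank over p came to within 1 of 15360, which is the number of genes in the authors' own adjustment. The table therefore lists 55.6% of the genes that the authors tested, and the others were not analysed here. Every count of genes given here is a count within that selection, and a second test on the same libraries is not independent of it.

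Gene symbols and coordinates are those of the deposited table, on GRCg6a, with positions as written there. Of the listed genes, 8244 had an entry in the RefSeq gene table used here by their NCBI Gene ID, and that table, made on another assembly, served for names and for chromosome names only.

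The expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled with TMM, genes were filtered with filterByExpr at its default settings, and dextran was set against control with the robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The filter removed 376 genes and left 8169. A standard error is the absolute log2 fold change divided by the square root of the F statistic. TPM is given as mean and SD of 3 libraries, and its ratios differ from the edgeR fold changes because TPM is scaled over all transcripts the authors quantified and TMM over the listed genes. TPM also divides by the length of the transcripts to which reads were assigned. An exact permutation test of 3 libraries against 3 cannot give a two-sided p below 0.1, so single genes were tested only within the model across genes.

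Depth was 10727497 to 10767267 listed counts per control library and 11475577 to 11755297 per dextran library. These sums cover the listed genes only. By the ratio of counts to FPKM the whole libraries were of nearly equal size, with relative totals of 0.978 to 1.00. The listed genes took 64.6% ± 0.031 of all TPM in the controls and 73.9% ± 0.275 with dextran (SD, n = 3 each), and the authors' size factors were lower with dextran by 0.35 on the log2 scale. Where a group had no count of a gene, a fold is given against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% counting interval, which covers counting error only.

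Before the data were examined, 26 gene lists, 6 marker lists of other cell types and the rule for named genes were fixed. The rule named the 6 largest increases and 6 largest decreases among genes past the threshold with a symbol, a mean of at least 2 CPM and no overlap between groups. It added the 3 or 4 members with the smallest adjusted p of each list, the genes with the smallest adjusted p in each direction, and, among others, MX1, IFIT5, OASL, IL1B, IL6, NOS2 and MARCO whatever their result. RSAD2, IFNB and MSR1 were also on that rule and were not analysed here. Some genes that met the rule are not reported here. Members that went against the direction of their list and the markers of other cell types were picked out after their values were seen. Symbols were matched to the deposited symbols and their listed synonyms, and 3 matches that pointed to another gene were dropped (ALAS2, SAA and MANF). Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 26 lists. That test sets a list against the other listed genes, which are themselves a selection. Members absent from the deposited table were not tested, so the counts of a list cover only members already called as different. Counts adjusted over a list alone were therefore nearly fixed beforehand and add no support. Marker lists had fewer tested members and are given as levels. Some genes belong to several lists, so the list tests are not independent of one another.

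The pipeline was tested on simulated counts for the same 8545 genes with 200 changed. It recovered 91.2% of the genes changed 1.5-fold, 97.1% of those changed 2-fold and 100% of those changed 4-fold, and called 7 unchanged genes. Limma-voom recovered 96% and DESeq2 1.42.0 recovered 95.5% of the changed genes. In the data, by contrast, 8009 of the 8169 tested genes differed. The simulation therefore does not show how the scaling and the tests behave when most genes change.

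Alternatives were RLE and upper-quartile scaling, DESeq2, limma-voom, no filter, a filter of 10 CPM in 3 samples, the replicate number as a block, a threshold of 0.01, a minimum absolute log2 fold change of 1, limma on log2(TPM + 1) and log2(FPKM + 1), leaving out each library in turn, and, for lists, fry and an estimated correlation. After the data were seen, scaling by the authors' recovered size factors, scaling by library totals and an adjustment over the authors' 15360 genes were added, as were tests of the pathways named in the deposited annotation and counts over gene families.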

Results

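The data are estimated counts, TPM and FPKM for 8545 genes in 3 control and 3 dextran libraries of HD11 cells, a chicken macrophage line. The sum of listed counts ran from 10727497 to 10767267 per control library and from 11475577 to 11755297 per dextran library. The series asks how dextran sulphate acts against viruses, and the comparison of dextran with control asks which transcripts changed in macrophages given it. All genes in the table had been called as different by the authors before deposit, so the counts below describe that selection.

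Transcripts of inflammatory mediators were far higher with dextran, and most interferon-stimulated genes were lower. CCL4, a chemokine that draws leukocytes, rose 108-fold, from 777 ± 21.8 to 64891 ± 3855 TPM (SD, n = 3 each), and NOS2, the inducible nitric oxide synthase, rose 252-fold, from 9.69 ± 0.469 to 1915 ± 138 TPM. IFIT5, an interferon-induced antiviral protein, fell 45.8-fold, from 178 ± 13.7 to 3.06 ± 0.390 TPM. Early response genes of growth factor signalling, a list of glycolysis and hypoxia response genes and amino acid stress genes were mostly higher. Complement component C1q, several Toll-like receptors and antigen presentation genes were mostly lower.

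Of the 8169 genes tested, 3941 were higher and 4068 lower with dextran in edgeR's quasi-likelihood test, and 160 did not pass the threshold. An absolute log2 fold change of at least 1 was reached by 1678 of the higher and 1606 of the lower genes. In the authors' deposited table, 4413 genes were higher and 4132 lower. The groups did not overlap for 98.0% of the tested genes, which the authors had selected on these same libraries. With limma on log2(TPM + 1) the split was 2409 higher and 4175 lower genes. Scaling by library totals moved the median log2 fold change of all tested genes by -0.26 and upper-quartile scaling moved it by -0.12, so small changes below are relative to the scaling.

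Among the largest increases were a pair of chemokine genes. IL8L1 (NCBI Gene ID 395872, chromosome 4, 50925090 to 50928168) rose by 10.81 ± 0.19 on the log2 scale (SE), and IL8L2 (396495, chromosome 4, 50937719 to 50940883), its neighbour, by 10.67 ± 0.16. Both are chicken relatives of interleukin 8, and reads shared between them make each value uncertain. MMP10, a matrix metalloproteinase (418981, chromosome 1, 183766311 to 183772932), rose by 10.78 ± 1.41, with 145 ± 131 TPM in the dextran libraries. Without dextran replicate 3 its value was 9.84. FSTL3, a secreted binder of activins (770427, chromosome 28, 2836657 to 2844986), had 0 control counts and 472 dextran counts and was at least 189-fold higher. KRT75, a keratin gene (408042, on a sequence for which no chromosome name was set here), had 0 and 251 counts and was at least 101-fold higher. EDPE (107049024, chromosome 25, 2335864 to 2339647) had 3 and 1995 counts, a ratio of 801 with a counting interval of 274 to 3886.

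Among the largest decreases were a lipid transporter pair and a receptor of microglia and macrophages. ABCA9 (417443, chromosome 18, 7924790 to 7947210) fell from 391 counts to 0 and was at least 108-fold lower. Its neighbour ABCA8 (417440, chromosome 18, 7902390 to 7923428) had 428 and 2 counts, a ratio of 178 with an interval of 48.9 to 1472. GPR34, a lysophosphatidylserine receptor (771199, chromosome 1, 113197820 to 113202590), fell by 9.34 ± 0.17, from 67.3 ± 4.77 to 0.080 ± 0.026 TPM. MMR1L2, a mannose receptor relative (428421, chromosome 2, 19428032 to 19462147), had 1327 and 3 counts, a ratio of 367 with an interval of 125 to 1784. Its copies lie in a gene family, so shared reads make that value uncertain. MDFIC (417774, chromosome 1, 25905660 to 25954293) had 181 and 1 counts, a ratio of 150 with an interval of 26.6 to 5971. SAMD9L, an interferon-induced restriction factor (420559, chromosome 2, 22910015 to 22918538), fell by 6.57 ± 0.28. The fitted log2 values of genes with few counts moved when 1 library was left out: EDPE reached 10.28 without control replicate 2, MMR1L2 -9.21 without dextran replicate 3 and MDFIC -8.81 without dextran replicate 1.

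Of 49 interferon-stimulated genes fixed beforehand, 35 were tested, of which 32 were lower and 3 higher, and the same numbers held adjusted over the list alone. The list stood below the other listed genes (camera, Benjamini-Hochberg adjusted p = 4.34e-07; adjusted p = 0.322 with an estimated correlation). EPSTI1 fell by 4.40 ± 0.16, MX1, a GTPase that blocks viruses, by 3.59 ± 0.26, and IFITM3, which restricts viral entry, by 3.24 ± 0.12. OASL fell by 2.48 ± 0.14. The 3 higher members were USP18, which restrains interferon receptor signalling, at 1.95, HELZ2 at 1.85, and EIF2AK2, a kinase activated by double-stranded RNA, at 0.84.

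Genes of interferon induction and interferon receptors were 7 higher and 8 lower of 15 tested, and equally adjusted over the list alone, with no call (camera, Benjamini-Hochberg adjusted p = 0.178). The higher count depended on the scaling: it was 5 under library totals, 4 with limma on log2(FPKM + 1) and 2 on log2(TPM + 1), and the lower count stayed at 8. TLR7, a sensor of single-stranded RNA, fell by 4.16 ± 0.11 in counts (mean TPM 40.5 to 0.980, a larger ratio), IRF5 by 1.89 ± 0.10 and the interferon receptor chain IFNAR2 by 1.05 ± 0.07. TRAF3, a signalling adaptor, rose by 2.36 ± 0.09. Interferon genes themselves were not analysed here.

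The inflammatory cytokines and mediators rose in 25 of 27 tested members and fell in 2, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.31e-17; adjusted p = 0.102 with an estimated correlation). IL1B rose by 8.32 ± 0.22, from 10.1 ± 0.275 to 2567 ± 832 TPM. IL6 rose by 2.01 ± 0.29 in counts and stayed low, with 23 control and 78 dextran counts in total. Its TPM went from 0.077 ± 0.023 to 1.29 ± 0.395, a larger ratio than that of the counts, and the cause was not tested. The 2 lower members were TNFSF10, a death receptor ligand, at -3.08 and the chemokine CCL26 at -1.74. CCL4 has near copies in the genome, so its share of the reads is uncertain.

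Genes that act in or respond to NF-kB signalling were higher in 19 of 23 tested members and lower in 4, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.31e-06; adjusted p = 0.102 with an estimated correlation). The feedback inhibitors TNFAIP3 and NFKBIA rose by 2.96 ± 0.10 and 2.41 ± 0.07. NFKB1 rose by 2.24 ± 0.06 and BIRC2, an inhibitor of apoptosis, by 2.14 ± 0.07.

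Of 39 early response genes of growth factor and MAP kinase signalling fixed beforehand, 29 were tested. All 29 were higher, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.96e-16; adjusted p = 0.102 with an estimated correlation). Of these, 27 passed the threshold under library-total scaling. The nuclear receptor gene NR4A3 rose by 6.58 ± 0.16, and the MAP kinase phosphatases DUSP1 and DUSP4 rose by 6.48 ± 0.12 and 4.28 ± 0.11. LOC100857932, which RefSeq names IER3, rose by 4.42 ± 0.10.

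**Figure D1:**
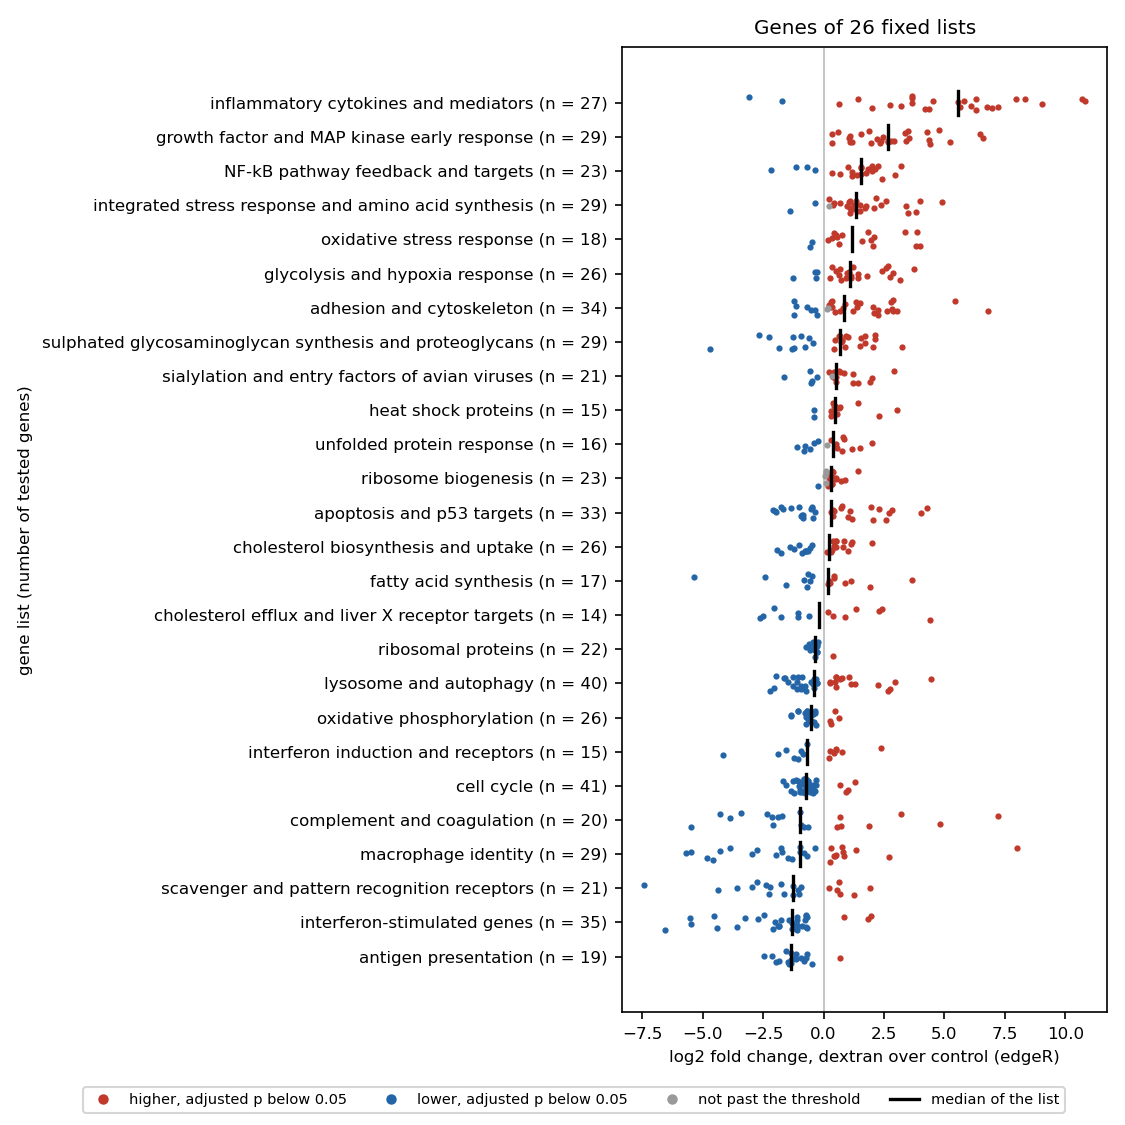
Each point is the log2 fold change of dextran over control (x axis, edgeR) of a tested gene in 26 lists fixed beforehand (y axis, with the number of genes tested), coloured by direction where the adjusted p lay below 0.05, with a black line at the median of the list. The inflammatory mediators have the highest median, 5.57, and the antigen presentation genes the lowest, -1.32.

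Macrophage genes were split. Of 29 tested macrophage identity genes 18 were lower and 11 higher, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000637; adjusted p = 0.272 with an estimated correlation). The higher count was 8 under library totals and 6 with limma on log2(TPM + 1). The C1q chain C1QA fell by 4.28 ± 0.09, the C1q chain C1QC fell by 5.46 ± 0.18, MPEG1, a pore-forming protein of phagocytes, fell by 4.59 ± 0.12, and C9ORF58, described in the table as an allograft inflammatory factor, fell by 4.81 ± 0.13. LYZ, lysozyme, was the furthest in the other direction, at 7.99, and its TPM went from 2.12 to 431. Markers of other cell types moved both ways. The epithelial genes CDH1 (6.06) and GRHL2 (5.52) were higher with KRT75, and KRT7 (-0.99) was lower. The granulocyte genes CATH3 (1.52) and MPO (1.48) were higher and CSF3R (-1.26) lower, and the B cell gene CD72 (3.20) was higher and BLNK (-3.64) lower. The T cell gene CD5 (-2.26), the erythroid gene TAL1 (-3.38) and the fibroblast genes COL3A1 (-2.32) and FBN1 (-0.37) were lower. With dextran the highest mean TPM among these markers was 82.6 for CSF3R, 18.4 for FBN1 and 5.85 for CDH1.

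Scavenger and pattern recognition receptors were lower in 15 and higher in 6 of 21 tested members, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00207; adjusted p = 0.272 with an estimated correlation). With limma on log2(TPM + 1), 3 members were higher. MARCO, a scavenger receptor for polyanions, fell by 3.59 ± 0.16, from 495 ± 30.5 to 32.4 ± 8.71 TPM, and STAB1 fell by 2.24 ± 0.07. The Toll-like receptors TLR2A and TLR1A fell by 4.37 ± 0.14 and 2.36 ± 0.13, although each has a near copy that can share its reads.

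Antigen presentation genes were lower in 18 of 19 tested members, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000651; adjusted p = 0.418 with an estimated correlation). CD74, the invariant chain of class II molecules, fell by 1.48 ± 0.11, ERAP1, which trims peptides, by 2.11 ± 0.11, MHCDMA by 1.84 ± 0.13 and LOC112529954, which has the synonym YFV, by 1.45 ± 0.09. CD1C, at 0.69, was the member that was higher. The pathway of antigen processing and presentation in the deposited annotation was tested after the data were seen. It was not called, with 7 members higher and 25 lower of 33 (camera, Benjamini-Hochberg adjusted p = 0.221).

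Complement and coagulation genes were lower in 13 and higher in 7 of 20 tested members, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.023; adjusted p = 0.418 with an estimated correlation). C1QB fell by 3.87 ± 0.13, while SERPINB2, an inhibitor of plasminogen activators, rose by 7.21 ± 0.24. C1QA, C1QB and C1QC are also members of the macrophage identity list, so the calls of these lists are not separate. SERPINB2 reached 7.87 without control replicate 2. The call of the complement list was lost without dextran replicate 3 (camera, Benjamini-Hochberg adjusted p = 0.176) and with the replicate number as a block (adjusted p = 0.068). The pathway of complement and coagulation cascades in the annotation was tested after the data were seen. It was not called, with 10 members higher and 18 lower of 28 (camera, Benjamini-Hochberg adjusted p = 0.206).

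Stress and metabolism genes followed. The integrated stress response and amino acid synthesis list was higher in 26 and lower in 2 of 29 tested members, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.17e-05; adjusted p = 0.272 with an estimated correlation). DDIT3, a stress-induced transcription factor, rose by 3.41 ± 0.12, the cationic amino acid transporter SLC7A3 by 2.08 ± 0.07, the tryptophan tRNA ligase WARS by 1.75 ± 0.07 and CEBPB by 1.35 ± 0.06. Oxidative stress response genes were higher in 16 and lower in 2 of 18, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000637; adjusted p = 0.272 with an estimated correlation). OSGIN1 rose by 3.87 ± 0.16, thioredoxin reductase TXNRD1 by 3.83 ± 0.12, MAFF by 3.38 ± 0.14 and SRXN1 by 2.06 ± 0.08.

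Glycolysis and hypoxia response genes were higher in 22 and lower in 4 of 26 tested members, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.58e-06; adjusted p = 0.272 with an estimated correlation). The hexokinase HK2 rose by 2.59 ± 0.08, the lactate transporter SLC16A3 by 2.76 ± 0.07, the glucose transporter SLC2A14 5.29-fold and EGLN3, a prolyl hydroxylase induced by hypoxia, by 2.86 ± 0.10. The pathway of glycolysis and gluconeogenesis in the deposited annotation, tested after the data were seen, was not called, with 16 members higher and 14 lower of 30 (camera, Benjamini-Hochberg adjusted p = 0.837). Oxidative phosphorylation genes were lower in 22 and higher in 4 of 26, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0294; adjusted p = 0.517 with an estimated correlation). ATP5I fell by 1.36 ± 0.08, and the complex I subunits NDUFA1, NDUFC2 and NDUFA10 fell by 1.36 ± 0.10, 1.04 ± 0.08 and 0.74 ± 0.06. The higher count was 2 under library totals and 0 with limma on log2(TPM + 1). Together with the ribosomal protein genes, these genes had a median of -0.45, and of -0.0789 after removal of the trend of log2 fold change with transcript length. The oxidative phosphorylation pathway of the annotation, also tested after the data were seen, was not called. In it 21 members were higher and 48 lower of 71 (camera, Benjamini-Hochberg adjusted p = 0.409).

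Adhesion and cytoskeleton genes were higher in 25 and lower in 7 of 34 tested members, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 6.61e-05; adjusted p = 0.124 with an estimated correlation). The integrin chain ITGB3 rose by 6.78 ± 0.10, from 2.02 ± 0.101 to 176 ± 20.1 TPM. VIM, the intermediate filament protein vimentin, rose by 2.87 ± 0.08, and the actin-binding protein ACTN1 rose by 2.24 ± 0.08.

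Sialylation and entry factors of avian viruses were higher in 15 and lower in 5 of 21 tested members, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.023; adjusted p = 0.322 with an estimated correlation). The higher count was 11 under library totals and 9 with limma on log2(TPM + 1). ST3GAL1, a sialyltransferase that makes alpha-2,3 linkages, rose by 2.92 ± 0.13, the chaperone HSPA5 by 2.00 ± 0.08, TNFRSF10B, the receptor of several avian leukosis virus subgroups, by 1.94 ± 0.07 and NANP, an enzyme of sialic acid synthesis, by 1.22 ± 0.06. The sulphated glycosaminoglycan list was not called, with 18 members higher and 11 lower of 29, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.196). The cell surface proteoglycans SDC1 and SDC2 rose by 2.13 ± 0.09 and 2.14 ± 0.07 and CD44 by 1.73 ± 0.06, while XYLT1, which starts the sugar chains, fell by 2.66 ± 0.11.

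Cell cycle genes were lower in 37 and higher in 4 of 41 tested members, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0054; adjusted p = 0.418 with an estimated correlation). CDK2 fell by 1.55 ± 0.09, CDCA7 by 1.21 ± 0.10, POLA1 by 1.00 ± 0.08 and CDT1 by 0.98 ± 0.08. The higher members were TK1 at 1.29, RFC3 at 1.00, CDC6 at 0.91 and E2F1 at 0.67. The cell cycle pathway of the deposited annotation was tested after the data were seen. It was not called, with 31 members higher and 49 lower of 80 (camera, Benjamini-Hochberg adjusted p = 0.664). Apoptosis and p53 target genes were split, 17 higher and 16 lower of 33, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.452): the cell cycle inhibitor CDKN1A rose by 4.02 ± 0.14, the survival factor MCL1 by 2.84 ± 0.09 and PLK3 by 2.73 ± 0.11, and the death promoter BID fell by 2.02 ± 0.07.

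Lipid genes moved both ways. Cholesterol biosynthesis and uptake had 14 members higher and 12 lower of 26, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.888), with a median of 0.23, a mean of -0.07 and a test direction of down. HSD17B7 rose by 2.02 ± 0.12 and SQLE by 1.15 ± 0.08, and FADS1 and LSS fell by 1.76 ± 0.11 and 1.20 ± 0.07. Fatty acid synthesis had 9 higher and 8 lower of 17, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.888), with a median of 0.17, a mean of -0.20 and a test direction of up. ACSL1 rose by 3.65 ± 0.15, the lipid droplet protein PLIN2 by 1.93 ± 0.07 and SREBF1 by 1.15 ± 0.06, and FADS2 was 5.28-fold lower. Cholesterol efflux and liver X receptor targets had 7 higher and 7 lower of 14, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.938), with a median of -0.20, a mean of 0.02 and a test direction of down. FABP5 rose by 2.41 ± 0.11 and PPARG by 2.30 ± 0.10, and the cholesterol ester hydrolase NCEH1 fell by 1.77 ± 0.08. Under library-total scaling the medians of the cholesterol biosynthesis and fatty acid lists were -0.03 and -0.09, with 8 and 5 members higher and 12 and 8 lower. With limma on log2(TPM + 1) 6 and 4 members were higher, so the balance of these lists depends on the scaling.

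In the other uncalled lists, counts adjusted over the list alone equalled those over all genes. Lysosome and autophagy genes were higher in 16 and lower in 24 of 40 (camera, Benjamini-Hochberg adjusted p = 0.452): ATP6V0D2, a proton pump subunit, rose by 4.46 ± 0.10 and GABARAPL1 by 2.67 ± 0.08, while HEXA and MCOLN1 fell by 2.03 ± 0.08 and 1.59 ± 0.06. In that list 9 members were higher with limma on log2(TPM + 1). Unfolded protein response genes were higher in 9 and lower in 6 of 16 (camera, Benjamini-Hochberg adjusted p = 0.286), with DNAJB9 at 1.51 ± 0.09, ERN1 at 0.86 ± 0.07 and HYOU1 at 0.75 ± 0.06. Heat shock proteins were higher in 13 and lower in 2 of 15 (camera, Benjamini-Hochberg adjusted p = 0.119), with HSPA2 at 3.02 ± 0.22, BAG3 at 2.28 ± 0.10, HSPB9 at 1.44 ± 0.16 and HSF2 at 0.66 ± 0.08, and 8 were higher under library-total scaling. That list was called without dextran replicate 3 (adjusted p = 0.0435 by camera with Benjamini-Hochberg adjustment). Ribosomal proteins were lower in 21 and higher in 1 of 22 (camera, Benjamini-Hochberg adjusted p = 0.135), with RPS28, RPL35, RPL38 and RPL31 at -0.71 ± 0.07, -0.61 ± 0.08, -0.55 ± 0.08 and -0.52 ± 0.07. Ribosome biogenesis genes were higher in 18 and lower in 1 of 23 (camera, Benjamini-Hochberg adjusted p = 0.118), with NOP14 at 1.44 ± 0.06, BYSL at 0.87 ± 0.07, UTP20 at 0.72 ± 0.06 and NOC3L at 0.51 ± 0.06, but 7 were higher and 4 lower under library-total scaling.

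**Figure D2:**
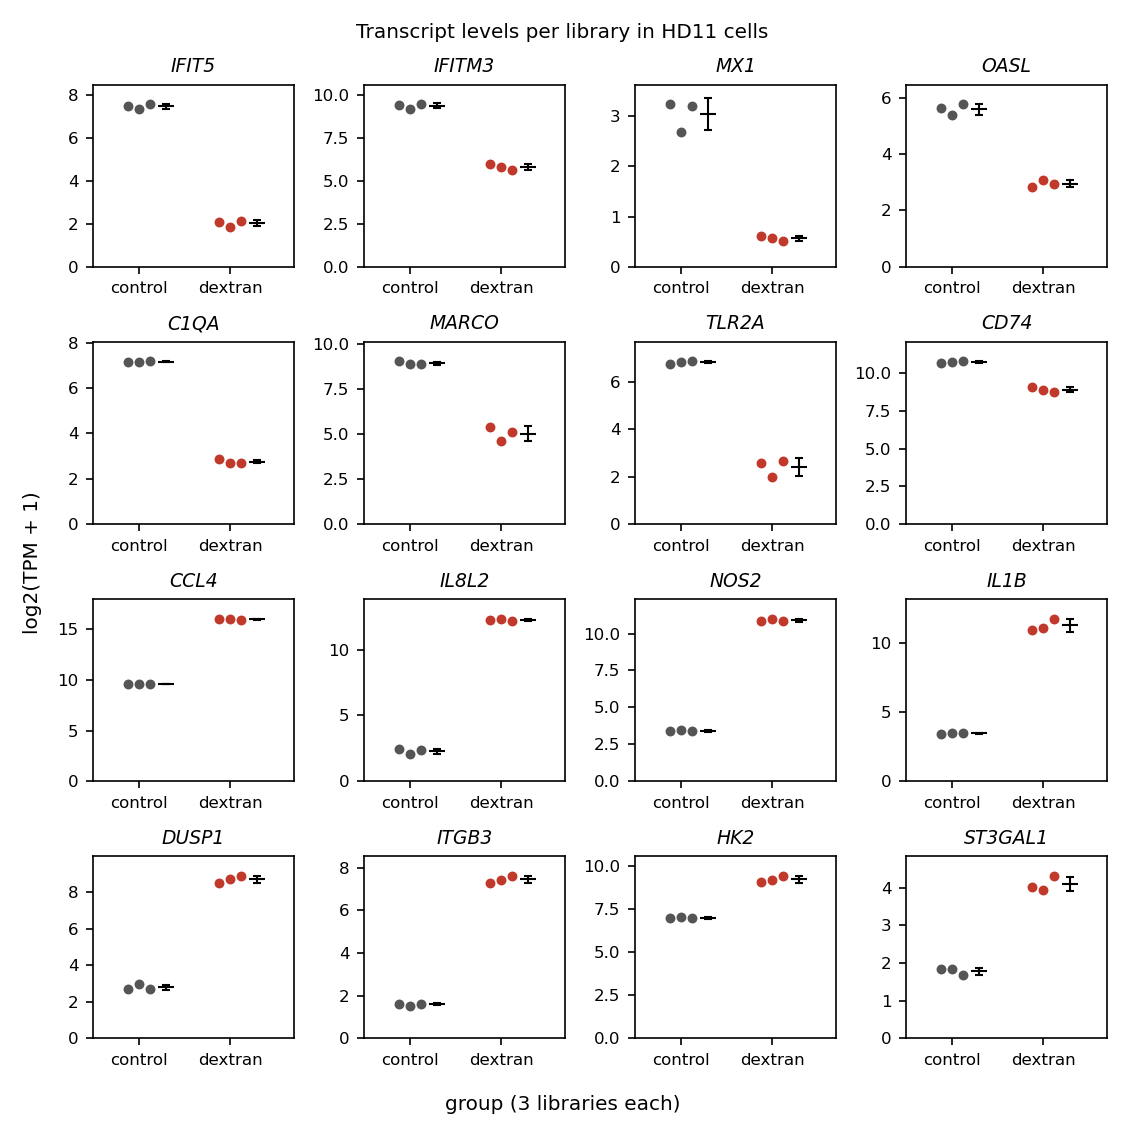
Each panel gives log2(TPM + 1) (y axis) of a gene in the 3 control and 3 dextran libraries (points), with the mean and SD of each group beside them. The groups are apart in all panels.

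All of the 15 list calls rest on the preset correlation between genes, and none held with an estimated one. The dextran libraries were less alike than the controls: the chi-square of counts over its degrees of freedom was 2.81 to 3.68 between controls, 5.31 between dextran replicates 1 and 2, and 25.8 and 29.3 between dextran replicate 3 and these.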

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

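Scaling by the authors' size factors, scaling by library totals and the adjustment over 15360 genes were chosen after the data were seen. The authors had already selected the listed genes on these libraries, so a steady number of calls was largely fixed beforehand and adds no support. The number of differing genes stayed within 1.5 times of 8009 under the other scalings, tests and filters, and with library totals it was 6925 (2812 higher, 4113 lower). Leaving out each library in turn gave 7800 to 8082. It fell to 3284 with an absolute log2 fold change of at least 1, to 1678 higher and 1606 lower genes, as the stricter threshold must give. With limma on log2(TPM + 1) 2409 genes were higher and 4175 lower. Of the 8009 genes, 6476 kept their direction and call, 658 had the opposite sign and 33 were called in the other direction. TPM is scaled over all transcripts. Under library-total scaling of the counts, 328 of the 8009 had the opposite sign and 0 were called in the other direction. How much of the change with TPM comes from scaling was not tested. With the replicate number as a block 7929 genes and 14 lists were called, the call of the complement list being the one lost. The numbers do not pair the libraries: same-numbered libraries deviated with correlations of 0.019, -0.071 and -0.049. Of 26 lists camera called 15, and 15 also with RLE scaling, the stricter filter, the authors' size factors, library totals and each library left out, though without dextran replicate 3 complement was lost and heat shock proteins gained. With an estimated correlation 0 lists were called (4 at an unadjusted p of 0.05), and fry, which does not compare a list with other genes, called 23. Counts of list members were recounted after the data were seen, and mostly those higher moved. With limma on log2(TPM + 1) they went from 7 to 2 for interferon induction and receptors, 14 to 6 for cholesterol biosynthesis, 9 to 4 for fatty acid synthesis, 11 to 6 for macrophage identity, 15 to 9 for sialylation and entry factors, 6 to 3 for scavenger receptors, 16 to 9 for lysosome and autophagy, 13 to 6 for heat shock proteins, 4 to 0 for oxidative phosphorylation, 1 to 0 for ribosomal proteins and 18 to 3 for ribosome biogenesis, where the lower count went from 1 to 5. Among named genes, NOC3L lost its call with limma on log2(TPM + 1) (0.07), and no named gene changed direction. A pseudocount of 0.1 and normalized values with no filter were planned for files without counts and were not run. The limit of depth is the selection: genes that the authors did not call were not analysed here.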

Other observations

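The gene families and annotation pathways here, and the tests of scaling, of the share of macrophages and of dextran replicate 3, were chosen after the values were seen. Of 7 tested matrix metalloproteinases, enzymes that cut extracellular matrix, all were higher with dextran. MMP1, a collagenase, went from 9.49 to 2444 TPM and MMP9, a gelatinase, from 11.2 to 1114 TPM (means, n = 3). MMP27 (6.27), MMP7 (5.63), MMP17 (1.69) and MMP2 (0.96) rose on the log2 scale with MMP10. Of 8 tested receptor genes with a symbol that starts with P2RY, 7 were lower, led by P2RY8 at -4.84, P2RY13 at -4.53 and P2RY12 at -4.42. P2RY4 was higher at 0.31, a call that was lost under library-total scaling. All 4 tested mannose receptor relatives were lower, with MMR1L3 at -5.23, MMR1L1 at -5.33 and MMR1L4 at -2.95 beside MMR1L2, and reads shared in this family make single values uncertain. The chemokine receptor CCR2 (-1.98) was lower and CXCR1 (1.81) was higher. Apart from P2RY4, these directions and calls were the same under upper-quartile, RLE and library-total scaling and without dextran replicate 3.

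In the deposited annotation 214 pathways had at least 15 tested genes, and 10 were called with camera. With an estimated correlation 0 were called after Benjamini-Hochberg adjustment and 11 passed at an unadjusted p of 0.05. The lysosome pathway was lower, with 64 members lower and 23 higher of 89 (camera, Benjamini-Hochberg adjusted p = 0.00916; adjusted p = 0.76 with an estimated correlation). Among its members DNASE2B fell furthest, by 3.06, then the metal transporter SLC11A1 by 2.34, the cholesterol carrier NPC2 by 2.21 and the ceramidase ASAH1 by 2.10. The proteases CTSV (2.73) and CTSD (2.25) and the proton pump subunits ATP6V0D2 (4.46) and ATP6V0A4 (3.57) were higher. Whether this differs from the fixed lysosome and autophagy list, which was not called, was not tested. Calcium signalling was higher in 65 and lower in 25 of 91 members (camera, Benjamini-Hochberg adjusted p = 0.0436; adjusted p = 0.76 with an estimated correlation), with the adenosine receptor ADORA2B at 7.24, from 2.11 to 252 TPM, PDGFA at 6.87 and the growth factor receptor FLT1 at 6.86. The pathway of receptors for extracellular matrix was higher in 27 and lower in 10 of 39 members (camera, Benjamini-Hochberg adjusted p = 0.00656; adjusted p = 0.76 with an estimated correlation), with the laminin chain LAMB3 at 2.86 among the higher. The other called pathways were IL-17, TNF, MAPK and NF-kappa B signalling, focal adhesion and a pair of cytokine receptor pathways, all higher.

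Interferon-stimulated genes were lower while inflammatory mediators were higher. Over 5 scalings the median of the tested interferon-stimulated genes was -1.20 at most and that of the inflammatory mediators 5.30 at least. The scalings moved the median of all tested genes by -0.26 to 0.09 only. That is too little to bring either list to 0, so this comparison could not decide on scaling. After removal of the trend with transcript length the interferon median was -1.23 (bootstrap 95% interval -1.82 to -1.04; -1.22 in a first fit that kept these genes), against -1.29 before, so length was not the whole cause. The bootstrap interval was not read as a spread between libraries, and the genes are not independent replicates. A lower share of macrophages alone would lower macrophage identity genes together, and 11 of 29 were higher. That count was 8 with library totals, 7 with limma on log2(FPKM + 1) and 6 on log2(TPM + 1). A gene raised within macrophages could be higher at any share, so these counts cannot decide on the share. All libraries are labelled as HD11 cells, a single line, and no label names another cell type. An effect of dextran stays open as a hypothesis, and how the cultures were handled, the timing and any impurity of the compound were not tested.

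The tested ribosomal protein and oxidative phosphorylation genes, most of them short, were mostly lower, with a median log2 fold change of -0.45 over 48 genes. They were 22 of 59 ribosomal protein genes and 26 of 48 oxidative phosphorylation genes fixed beforehand. The others were not analysed here, so the median describes genes already called as different and not these classes as a whole. Over 5 scalings the median was -0.36 at most. These scalings moved the median of all tested genes by -0.26 to 0.09. That is too little to bring -0.45 to 0, so this comparison could not decide on scaling either. After removal of the trend with transcript length, fitted on the other genes, the median was -0.0789 (bootstrap 95% interval -0.19 to -0.02); a first fit on all genes gave -0.06, and leaving these genes out of the fit was decided after that. This interval, too, was not read as a spread between libraries, and the genes are not independent replicates. The trend ran from -0.20 at the 10th percentile of length to 0.05 at the 90th. Across genes, log2 fold change went with length only weakly (Spearman rho 0.068). A bias with length may carry some of this decrease. How much cannot be told, because a true change shared by short transcripts would give the same trend.

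Dextran replicate 3 stood apart from dextran replicates 1 and 2, with 375 of 6712 genes of at least 10 CPM differing by 0.5 or more on the log2 scale from their mean. MMP10 (1.98), CSF3 (1.59), SLC7A11 (1.47), VIP (1.33) and PLAU (1.11) were higher in it, and OSTN (-2.19), CAMK2A (-1.36) and CXCR1 (-1.23) lower. Without it the log2 fold changes of CSF3 and SLC7A11 went from 9.02 to 8.29 and from 3.98 to 3.32. Its differences went with transcript length (Spearman rho 0.234 across genes, which are not independent replicates), yet removing that trend lowered their median absolute deviation by 4.03% and left 314 of the 375 genes past 0.5, which argues against length as the whole cause. With the fold change fitted without it rho was 0.158 and removing that trend lowered the deviation by 1.86%; a response further along need not follow the fold change, so it stays open.

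The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 8009 genes in edgeR after Benjamini-Hochberg adjustment, the only 1 with as many, and the highest other split gave 0. The authors had selected these genes for differing in the real split, so the contrast was fixed beforehand and decides nothing.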
